A study of Mus musculus with 6 samples.

How the data were processed

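Macrophages were grown from mouse bone marrow in medium with 10% serum, 1% antibiotic and 20 ng/mL of macrophage colony-stimulating factor, per the labels' protocols. Conditioned medium of injured pancreatic acinar cells (PAC-CM) was added on day 5, with or without 400 µM kinsenoside. Per the labels' protocols, 1 µg of total RNA went into each library after mRNA enrichment, and libraries were read as 150-nucleotide pairs on a NovaSeq 6000. The library kit is named in the labels, but whether it keeps strand is not. All 6 samples have a group in the labels, with 3 per group, and entered a single comparison.

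The deposited table gives whole-number counts per Ensembl gene, 1 column per library, for 55335 genes. The submitters' processing notes name bcl2fastq 2.20, FastQC 0.11.2, STAR, StringTie 1.3.1c, DESeq2 1.16.1 and the build GRCm38, with no role or order. Which tool made the counts the authors deposited is not given in the sources used here. Among low values, a count of 3 (6202 cells) was more frequent than 2 (5128) and 5 (3084) more frequent than 4 (2444), so the counts may be rounded estimates. If an assembler made them, reads of overlapping gene models can pass from one model to another between libraries. Of the identifiers, 55154 are in the GENCODE M21 annotation of the same build, which gave coordinates, gene types, transcript lengths and GC content; gene symbols are those of the deposited table, in which 3225 identifiers have none. Strand use in the counting is not stated, so overlapping and antisense genes cannot be told apart.

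The counts were used as deposited. The main test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr, which kept 13901 genes, TMM normalization, robust dispersion and quasi-likelihood fits on the group alone with 4 residual degrees of freedom, and a two-sided test with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Log2 CPM, used for principal components and for the median of a list in each library, was scaled by the TMM factors with a prior count of 2. Values given as CPM are counts divided by the library total, as mean ± SD over 3 libraries. A floor of 3 counts per library was used for genes at 0.

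A total of 52 gene lists, 41 of pathways and states and 11 of cell type markers, were written from general knowledge before the data were examined, and 50 with at least 5 tested members were compared with all other genes by camera, with a preset correlation of 0.01 and again with an estimated correlation, and by fry. Adjustment was over the lists tested. The setting with an estimated correlation is stricter apart from the correlation itself. For the list of M1 macrophage genes the estimate was -0.02, below the preset, yet the unadjusted camera p went from 3.7e-07 to 0.00494. A list that misses in that setting is thus not shown to have correlated members. Lists share genes (Il1b, Irf1 and Cxcl10 are in several), so their results are not independent. Genes named in the text were chosen by a rule fixed beforehand. It took the 10 higher and 10 lower genes of largest fold change with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, without clone or model names. It added the 5 of smallest p per direction, up to 4 called members of each list (or the 2 most abundant if none was called), and 18 panel genes, of which 1 is not reported here. Other names are said to be chosen afterwards or illustrate a count adjusted over a list alone.

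The alternatives were DESeq2 1.42.0 and limma-voom, RLE, upper quartile and total count scaling, no filter or a filter of more than 1 CPM in at least 3 libraries, the replicate number as a block, non-robust estimates, leaving out mitochondrial genes and the 20 most abundant genes, leaving out each library, a threshold of 0.01, glmTreat against a log2 fold change of 1, and principal components of the 500 most variable genes. Chosen after seeing the data were a correction for transcript length and GC content (loess trends per library, fitted without list genes), lists without their called members, and a count without genes whose values jump between libraries.

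The edgeR script was tested on simulated counts for the comparison of kinsenoside with PAC-CM, drawn for 13901 genes from the libraries' means, depths and dispersions with 200 genes changed. It recovered 31 of 67 genes changed 1.5-fold, 45 of 67 changed 2-fold and 61 of 66 changed 4-fold, all with the right sign. Of 149 genes called in that simulation 12 had not been changed, and with no gene changed 2 were called. For the list test on the same 13901 simulated genes, a list raised 1.3-fold was called and none of 49 unchanged lists was. Simulated genes were drawn independently of each other. This result therefore does not measure false calls of lists whose members move together, such as the ribosomal list (estimated correlation 0.651). With 3 libraries per group, changes under 1.5-fold are missed more often than not at this depth.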

Results

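The series holds RNA-seq gene counts from mouse bone marrow-derived macrophages, primary cells grown from bone marrow with macrophage colony-stimulating factor. All 6 libraries came from macrophages given medium conditioned by injured pancreatic acinar cells (PAC-CM), the enzyme-secreting cells of the pancreas. In 3 libraries the medium was given alone, and in 3 it was given with 400 µM kinsenoside, a plant glycoside. The design asks what kinsenoside does to macrophages exposed to signals of injured pancreas, a cell culture setting for acute pancreatitis. No macrophages without conditioned medium are among the samples, so the values show the difference made by kinsenoside and not the response to the medium. The total counts were 43054066, 47461702 and 44113604 in PAC-CM replicates 1 to 3, and 43434292, 42199166 and 41125059 in kinsenoside replicates 1 to 3. At this depth 3 counts, taken as the limit below which a gene at 0 cannot be called absent, correspond to between 0.0632 and 0.0729 CPM (a count scaled by the library total), which covers counting error only. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

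The groups separated along the first principal component of log2 CPM, which held 28.8% of the variance. PAC-CM libraries lay between -25.7 and -11.9 on it, and kinsenoside libraries between 4.29 and 30.7. The separation was weaker for kinsenoside replicate 1. Over the 500 most variable genes it lay at -0.44 on the first component, nearer PAC-CM replicate 3 (-8.80) than kinsenoside replicates 2 and 3 (19.7 and 18.7). Its log2 CPM correlated across genes at 0.9851 with PAC-CM replicate 2, against 0.9836 and 0.9817 with kinsenoside replicates 2 and 3. The second component held 23.6% and set kinsenoside replicate 1, at -39.3, apart from the other libraries, which lay between -6.13 and 19.7. No pair of libraries was alike within sampling noise, since the chi-square per degree of freedom over genes was between 24.1 and 58.7 in all pairs.

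**Figure D1:**
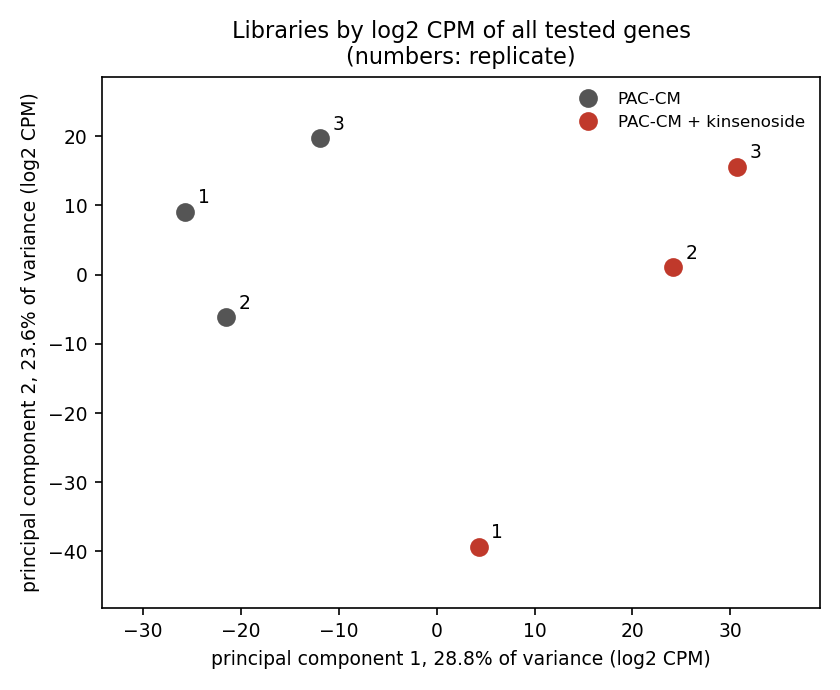
Position of the 6 libraries on the first 2 principal components of log2 CPM over all tested genes, with the share of variance on each axis (28.8% and 23.6%), grey for PAC-CM and red for PAC-CM + kinsenoside, numbered by replicate. The 3 kinsenoside libraries lie at 4.29 or above on the first component and the 3 PAC-CM libraries at -11.9 or below, while kinsenoside replicate 1 lies alone at -39.3 on the second.

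Several inflammatory transcripts were lower in PAC-CM macrophages given kinsenoside. Irf1, a transcription factor of the interferon response, fell from 153 ± 8.30 to 84.4 ± 2.75 CPM (SD, n = 3 per group), and Cxcl10, an interferon-induced chemokine, fell from 557 ± 48.2 to 285 ± 24.5 CPM. The interleukin-1 cytokine genes fell as well, Il1b from 1585 ± 58.4 to 1016 ± 70.3 CPM and Il1a from 1184 ± 63.8 to 650 ± 113 CPM. In the other direction, Clec4n, which encodes the fungal pattern receptor Dectin-2, rose from 144 ± 23 to 320 ± 18.8 CPM, the chemokine gene Ccl6 from 186 ± 13.1 to 377 ± 41.8 CPM, and Mrc1, the mannose receptor used as a marker of alternatively activated macrophages, from 93.7 ± 5.84 to 143 ± 14.8 CPM. Each of these genes had all 3 libraries of one group above all 3 of the other, as had all 71 genes called in the test below. The naming rule asked for this in part, so it is no separate support.

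In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 71 of 13901 tested genes differed, 29 of them higher and 42 lower with kinsenoside. Most changes were small: 16 of the 71 had a fold change of at least 2, with 11 higher and 5 lower. At an unadjusted p under 0.05 there were 2075 genes. The 3 libraries of one group lay above the 3 of the other for 3130 tested genes, or 22.5%, where chance gives 10%. The number of calls depended on the test and on single libraries: DESeq2 called 415 genes and limma-voom 39. Leaving out 1 library gave between 13 calls, without PAC-CM replicate 1, and 98, without kinsenoside replicate 1. The balance of directions changed too: 40.8% of calls were higher with all libraries, and between 48.0% and 75.0% with 1 library left out. Without PAC-CM replicate 1 there were 8 higher and 5 lower calls, and without PAC-CM replicate 3 there were 8 and 6. Each set of 8 included Hist2h2aa1, Gm20634, Gm15925, Arl2bp and Socs6. Their jumps in counts between libraries may come from read assignment, as described below, so these shares lean on genes of uncertain counts.

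Among the lowered genes, Irf1 (ENSMUSG00000018899, chromosome 11, 53770014 to 53778374, GRCm38) had a log2 fold change of -0.81 (SE 0.0672, adjusted p = 0.00248), and Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) of -0.92 (SE 0.0867, adjusted p = 0.00482). Spata13 fell by 0.87 on the log2 scale (SE 0.0767, adjusted p = 0.00379). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) had -0.60 (adjusted p = 0.0152), and Il1a -0.82 (adjusted p = 0.0403). Over 17 alternatives, which include leaving out each library, Il1b passed in 13 (adjusted p up to 0.0824) and Il1a in 10 (up to 0.157). The deepest fall among genes with a mean of at least 5 CPM was that of Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269), the receptor of Cxcl10, at -1.64 (SE 0.228, adjusted p = 0.0316; passed in 11 of the 17), from 8.80 ± 1.32 to 2.73 ± 0.889 CPM. Olr1, the scavenger receptor for oxidized low-density lipoprotein, followed at -1.17 and Haghl at -0.97. Itgb8, an integrin subunit, had -0.90, Map3k5, the stress kinase ASK1, had -0.81, the transcription factor Runx3 had -0.75 and the adaptor gene Apba1 had -0.72, with adjusted p between 0.0152 and 0.0473 for these 6 genes.

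Among the raised genes, Clec4n (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021) had a log2 fold change of 1.19 (SE 0.116, adjusted p = 0.00767) and Ccl6 (ENSMUSG00000018927, chromosome 11, 83587882 to 83593087) of 1.07 (SE 0.0968, adjusted p = 0.00405). Kidins220, a membrane scaffold of neurotrophin signalling, had 1.12 (SE 0.0820, adjusted p = 0.00129). Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) had 0.66 (SE 0.0924, adjusted p = 0.0316). It passed in 10 of the 17 alternatives (adjusted p between 6.24e-07 and 0.127), but not with limma-voom, the replicate block or non-robust estimates, nor without any 1 of the PAC-CM libraries or without kinsenoside replicate 3. Prdx6, a peroxiredoxin that reduces lipid peroxides, had 0.65 (adjusted p = 0.0184), rising from 462 ± 25.9 to 701 ± 49.9 CPM, and Cd28, a costimulatory receptor best known from T cells, had 0.67 (adjusted p = 0.0412). Hspa1a and Hspa1b, the inducible Hsp70 genes, had 0.63 and 0.75 (adjusted p = 0.0403 and 0.0473); their coding sequences are nearly identical, so reads can be split between them and the separate values are uncertain.

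Hist2h2aa1, Arl2bp and Socs6 were the raised genes of largest fold change among the called genes named by rule. Hist2h2aa1, a histone H2A gene (ENSMUSG00000064220, chromosome 3, 96245497 to 96246082), had 0 counts in each PAC-CM library and 717, 657 and 641 in the kinsenoside libraries (adjusted p = 3.84e-05). Against a floor of 3 counts per library, it was at least 237-fold higher. The overlapping transcript gene Gm20634 went from 0 in each PAC-CM library to 133, 119 and 100 counts. Hist2h3c1, which lies wholly within Gm20634 and whose reads cannot be told from it, went from 195, 163 and 184 counts to 68, 63 and 51, a loss close to the gain of Gm20634; both were chosen after their values were seen. Arl2bp, a binding partner of the GTPase Arl2, had a log2 fold change of 1.60 and Socs6, of the suppressor of cytokine signalling family, of 1.58 (adjusted p = 0.00105 and 0.00129). Hist2h2aa1, Arl2bp and Socs6 belong to 126 genes found among 9744 with a highest count of at least 200. Counts of these 126 jump between libraries at least 2-fold with tight values on either side, and 122 of those jumps do not follow the groups.

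**Figure D2:**
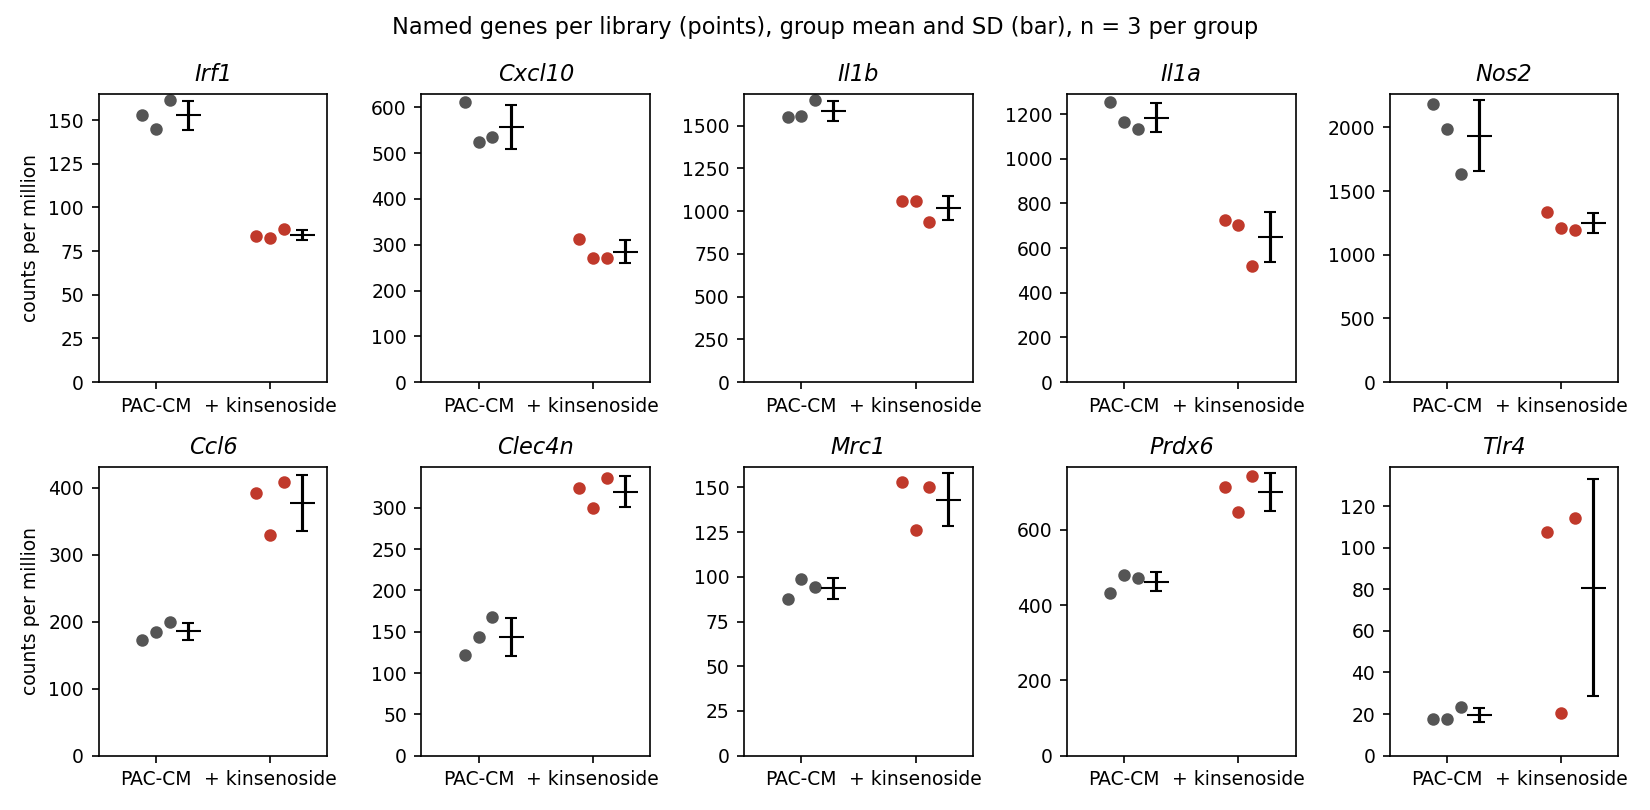
CPM of 10 genes in each library (points: grey, PAC-CM; red, PAC-CM + kinsenoside; 3 libraries per group), with the group mean and SD beside them; every axis starts at 0. Irf1, Cxcl10, Il1b and Il1a fell and Ccl6, Clec4n, Mrc1 and Prdx6 rose past the threshold, Nos2 missed it (adjusted p = 0.0640), and Tlr4 was high in 2 of the 3 kinsenoside libraries.

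Of the gene lists fixed before the data were examined, 3 inflammatory ones lay below other genes by camera with its preset correlation: NF-kB targets, M1 genes, and interferon-gamma GTPases and targets (adjusted p = 3.17e-08, 3.08e-06 and 0.000235). With an estimated correlation none of them passed (adjusted p = 0.381, 0.247 and 0.264). Of 29 tested NF-kB inflammatory targets, 4 fell (Il1a, Il1b, the NF-kB inhibitor gene Nfkbia at -0.56 and Nfkbiz at -0.48) and none rose. Of the 29 estimates, 22 lay below 0 and the median was -0.23. The list of 23 M1 genes, those of classically activated macrophages, had 3 falling members (Irf1, Cxcl10 and Il1b) and 20 that did not pass. Its median was -0.16. Of 29 interferon-gamma GTPases and targets, Irf1 and Cxcl10 fell, and 27 did not pass, with a median of -0.11. Adjusted over the list alone, 6, 7 and 6 members fell in the NF-kB, M1 and interferon-gamma lists, among them Nfkbie, Nos2 and Gbp5, and no member rose. By fry, which asks whether a list moves on balance in either direction without reference to other genes, the M1 and interferon-gamma lists passed (adjusted p = 0.0143 for both) and the NF-kB list did not (adjusted p = 0.103). Without their called members, the M1 and interferon-gamma lists missed the threshold (adjusted p = 0.0675 and 0.0620), with a range of 9.79e-07 to 0.247 and 5.48e-05 to 0.264 over all alternatives. Of 36 type I interferon-stimulated genes, Cmpk2, a mitochondrial nucleotide kinase, fell by 0.49 and Rsad2, the antiviral protein viperin, fell by 0.42 on the log2 scale. The other 34 did not pass (camera adjusted p = 0.324), with the same count of 2 lower when adjusted over the list alone. The call of Rsad2 (edgeR adjusted p = 0.0473) was lost with limma-voom, RLE scaling, the replicate block, non-robust estimates and whichever library was left out.

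Chemokine genes went both ways. Of 22 tested chemokines, Ccl6 and Ccl9 rose, Ccl9 by a log2 fold change of 0.51 (from 710 ± 57.8 to 979 ± 59.9 CPM, adjusted p = 0.0415), and Cxcl10 fell, while 19 did not pass. Adjusted over the list alone, 3 rose and 1 fell. The point estimates lay above 0 for 18 of the 22, with a median of 0.50, and camera placed the list above other genes (adjusted p = 3.08e-06; adjusted p = 0.381 with an estimated correlation). The list's median log2 CPM relative to each gene's mean was 0.58 in kinsenoside replicate 1, which stood apart on the second component, against 0.10 in both other kinsenoside libraries and -0.33, -0.09 and -0.18 in the PAC-CM libraries. Without that library camera gave an adjusted p of 0.000443 (range over the alternatives 2.24e-08 to 0.381). By fry the chemokine list did not pass (adjusted p = 0.191). Among 16 chemokine and chemoattractant receptors Cxcr3 fell and 15 did not pass. That list missed the threshold (camera adjusted p = 0.0573), with 4 members lower when adjusted over the list alone.

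Several lists of phagocytic, lipid and protective functions lay above other genes by camera with its preset correlation, mostly with few members past the threshold, and none of these lists passed with an estimated correlation (adjusted p = 0.300 or above). Of 34 phagocytosis and efferocytosis receptors, Mrc1 rose and 33 did not pass, while adjusted over the list alone 4 were higher (median 0.13, camera adjusted p = 0.00217; 0.300 as the adjusted p with an estimated correlation). Of 20 heat shock genes Hspa1a and Hspa1b rose, and adjusted over the list alone 4 were higher (median 0.19, adjusted p = 0.000117; adjusted p = 0.381 with an estimated correlation). Plin2, the coat protein of lipid droplets, rose from 2342 ± 60.4 to 3019 ± 46.4 CPM (log2 fold change 0.41, adjusted p = 0.0299) and was the single call among 25 fatty acid oxidation and PPAR targets (median 0.04, camera adjusted p = 0.0320; adjusted p = 0.300 with an estimated correlation) and among 24 hypoxia targets (camera adjusted p = 0.895). Adjusted over the list alone, 5 of the fatty acid oxidation and PPAR targets were higher (Plin2, Cd36, Fabp4, Fabp5 and Pparg), and 1, Cpt1a, was lower. None of the 5 encodes an enzyme of fatty acid oxidation. Estimates of the oxidation genes lay on both sides of 0, from -0.27 for Cpt1a to 0.17 for Etfdh. The list's position thus does not show a rise of oxidation genes as a group. No member was called over all genes in the NRF2 antioxidant list (27 tested, 23 estimates above 0, median 0.20), but adjusted over the list alone 11 were higher, among them the glutathione genes Gclm and Gsr and the ferritin light chain gene Ftl1. Camera gave this list an adjusted p of 3.08e-06, and the adjusted p with an estimated correlation was 0.300. The lists of lysosome and TFEB targets (44 tested, median 0.09), macrophage identity (27 tested identifiers, 0.15), iron handling and ferroptosis (24 tested, 0.11), LXR targets and cholesterol efflux (19 tested, 0.16) and autophagy (28 tested, 0.10) also lay above other genes by camera, at adjusted p between 0.00162 and 0.0346. With an estimated correlation their adjusted p was between 0.300 and 0.385. Adjusted over the list alone, 1, 0, 1, 2 and 1 of their members were higher and none was lower. The calls of the fatty acid oxidation and PPAR list, the autophagy list and the LXR list were each lost without kinsenoside replicate 3 (camera adjusted p = 0.0604, 0.104 and 0.0522). The first 2 were also lost without PAC-CM replicate 1 (0.0861 for both) or 2 (0.0546 and 0.0617), and autophagy without kinsenoside replicate 1 (0.0510). Over the alternatives the adjusted p ranged from 0.00564 to 0.300 for fatty acid oxidation and PPAR targets. It ranged from 0.00355 to 0.300 for autophagy and from 0.00167 to 0.377 for LXR targets. By fry the iron handling list, the autophagy list and the list of fatty acid oxidation and PPAR targets passed (adjusted p = 0.0143, 0.0159 and 0.0345). The phagocytosis, heat shock, NRF2, lysosome, macrophage identity and LXR lists did not pass by fry (adjusted p between 0.0671 and 0.141).

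All 47 tested cytosolic ribosomal protein genes had estimates above 0, with a median of 0.25, or 1.19-fold. None was called over all genes, while adjusted over the list alone 29 were higher. Rplp1, for example, was at 276 ± 18.3 CPM in PAC-CM and 318 ± 18.1 CPM with kinsenoside (adjusted p = 0.183). The list's share of all counts was 0.632%, 0.639% and 0.697% in the PAC-CM libraries and 0.691%, 0.730% and 0.809% in the kinsenoside libraries, so the groups overlapped in this share. They did not overlap in the list's median log2 CPM after TMM scaling, relative to each gene's mean. This was -0.20, -0.15 and -0.04 in the PAC-CM libraries and 0.02, 0.09 and 0.26 with kinsenoside. The TMM factors were 1.013 to 1.019 in the PAC-CM libraries and 0.979 to 0.99 with kinsenoside. Such scaling raises the kinsenoside values relative to the share of counts, so the separation may rest in part on it. Of 52 nuclear-encoded oxidative phosphorylation genes, 44 estimates lay above 0 (median 0.11), and 2 were higher when adjusted over the list alone. Of 15 mitochondrially encoded genes 14 lay above 0 (median 0.18), and none was higher. Camera placed the lists above other genes (adjusted p = 1.29e-16, 3.08e-06 and 0.00162), whereas with an estimated correlation the adjusted p was 0.433, 0.264 and 0.895. By fry the ribosomal and mitochondrial lists missed (adjusted p = 0.117 and 0.444) and the oxidative phosphorylation list passed (0.0143). The mitochondrial list's median log2 CPM relative to each gene's mean was -0.10 in kinsenoside replicate 1, within the PAC-CM range of -0.14 to -0.01. It lost its call without kinsenoside replicate 3 (adjusted p = 0.193; range over the alternatives 2.77e-07 to 0.895).

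**Figure D3:**
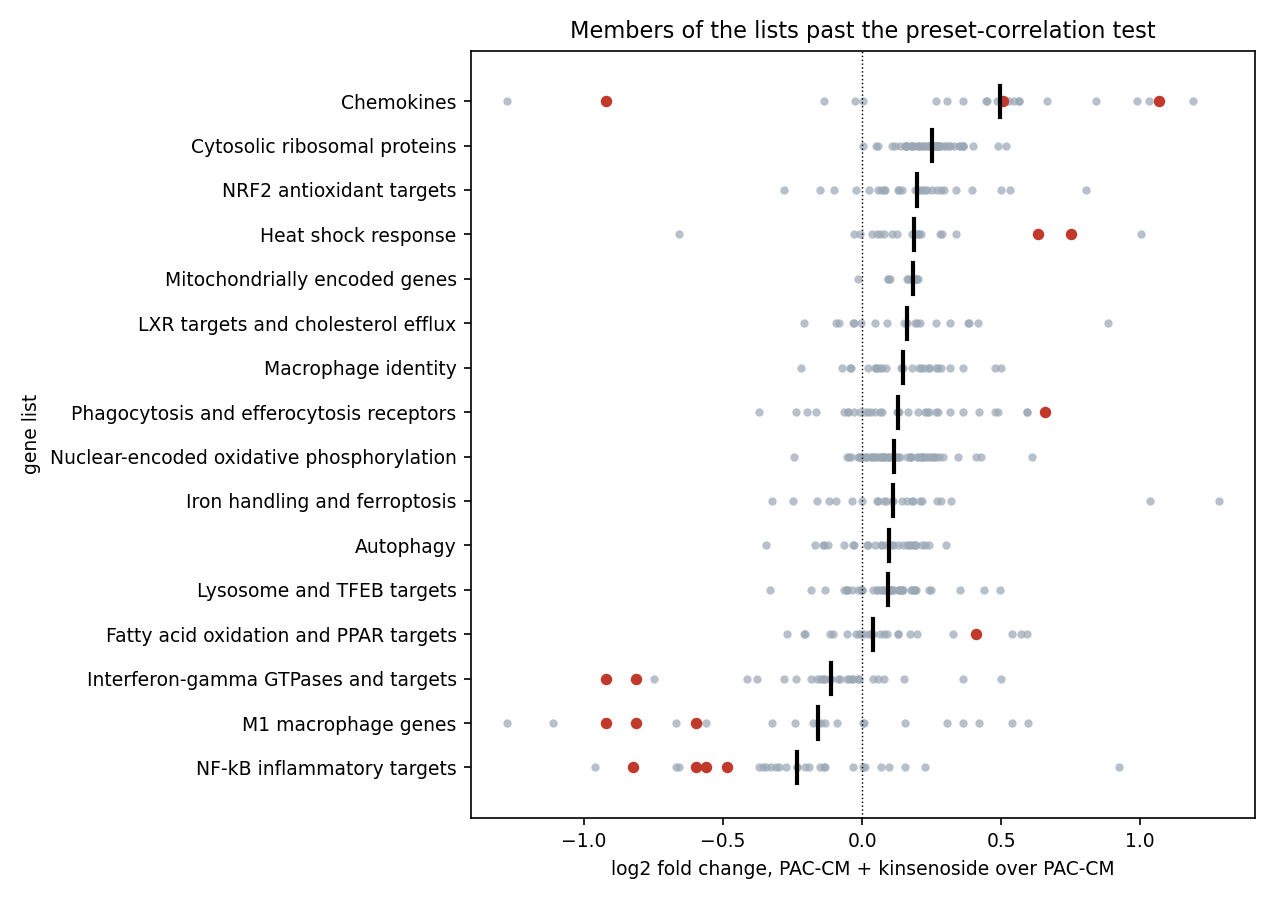
Log2 fold change of kinsenoside over PAC-CM for each tested member of the 16 gene lists past the camera test with the preset correlation; each point is a gene, red where its adjusted p was under 0.05, and the black bar is the list's median. Medians run from -0.23 for NF-kB inflammatory targets to 0.50 for chemokines, and most members of each list did not pass by themselves.

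Of 18 panel genes of macrophage activation, Il1b and Cxcl10 fell, Mrc1 rose, and 14 others were tested without passing. Nos2, the inducible nitric oxide synthase, was at 1936 ± 278 CPM in PAC-CM and 1247 ± 78.2 CPM with kinsenoside (log2 fold change -0.59, adjusted p = 0.0640). Its adjusted p ranged from 4.45e-05 to 0.230 over the other settings, and it was called in 6 of these 17 settings. Tnf had a log2 fold change of -0.67 (adjusted p = 0.203), Il10 of -0.42 (0.117) and Nlrp3 of -0.33 (0.182). Arg1, the arginase of alternatively activated macrophages, had 0.70 (adjusted p = 0.322), with large spread (520 ± 129 and 821 ± 211 CPM), and Ccl2 had 0.45 (0.421). Estimates of Il6, Cd86 and Hmox1 lay between 0.00 and 0.08. Ptgs2 had -0.13 (0.755), while Il12b and Chil3 were at under 4 CPM in both groups. Tlr4 (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284), the receptor of lipopolysaccharide, had 756, 837 and 1025 counts in the PAC-CM libraries and 4663, 873 and 4701 with kinsenoside. Its log2 fold change of 2.10 (SE 0.708) did not pass (adjusted p = 0.297), and without kinsenoside replicate 2 it was 2.56 (adjusted p = 0.00149, with a range of 0.00149 to 0.549 over the alternatives). Retnla had 0 counts in all 6 libraries and was not detectable at this depth.

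The M2 list, genes of alternatively activated macrophages, had Mrc1 as its single call among 23 tested members and a median of 0.17. It missed the threshold (camera adjusted p = 0.0520), and adjusted over the list alone 4 members were higher and 2 lower. A total of 34 of the 50 tested lists did not pass, with adjusted p between 0.0520 and 0.944. Besides those named above and the 9 tested lists of cell type markers, they were the lists of Toll-like receptor signalling, inflammasome and pyroptosis, antigen presentation by MHC class I and class II, glycolysis, the pentose phosphate pathway, the TCA cycle, cholesterol synthesis, integrated stress and unfolded protein responses, complement, immediate early genes, S and G2/M phases, p53 targets, apoptosis, matrix remodelling, lipid mediators, JAK-STAT regulators, growth factors and replication-dependent histones. Among these, Il1b in the inflammasome list was the single member called over all genes. Adjusted over the list alone, 3 members were lower in the Toll-like receptor list (Tlr1, Tlr2 and Tlr3) and 3 in the JAK-STAT list, and the others but glycolysis had at most 1 in either direction. Glycolysis had 21 tested members and a median of -0.01 (adjusted p = 0.479), with Pkm at 4351 ± 99.3 and 4472 ± 263 CPM, while adjusted over the list alone 4 members were lower (Hk2, Pfkm, Pfkfb3 and Pfkp) and none was higher.

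No list of markers of other cell types that was large enough to test passed. The 9 such lists (pancreatic acinar cells, neutrophils, monocytes and myeloid progenitors, dendritic cells, lymphocytes, endothelial cells, erythroid cells and platelets, mast cells with basophils and eosinophils, and osteoclasts) had camera adjusted p between 0.289 and 0.921, with no member called over all genes. Adjusted over the list alone, the neutrophil collagenase gene Mmp8 was higher (log2 fold change 1.47, adjusted p = 0.0716 over all genes), the monocyte marker Ly6c2 was lower, and of the osteoclast markers Ctsk and Atp6v0d2 were higher and Nfatc1 and Tnfrsf11a lower. The fibroblast list, with 4 tested members, and the pancreatic duct and islet list, with 2, were too small for the list test. Transcripts of acinar cells, the source of the conditioned medium, were at trace level: the marker genes together had between 7.90 and 11.1 CPM per library, and Cela1, a pancreatic elastase, had 3.13 ± 0.676 CPM in PAC-CM and 2.2 ± 0.366 CPM with kinsenoside (adjusted p = 0.353).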

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

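The length and GC correction, the lists without their called members and the count without step genes were chosen after seeing the data. With edgeR's TMM fit, 71 genes differed (29 higher, 42 lower), 16 of them at least 2-fold (11 higher, 5 lower). DESeq2 called 415 (177 higher, 238 lower), including all 71, and 51 at 2-fold (21 and 30); limma-voom called 39 (19 and 20), with 2 at least 2-fold lower. With the replicate number as a block there were 42 (17 and 25), 32 of them among the 71. The numbers do not pair the samples by the labels, and same-number libraries' deviations correlated at 0.01, -0.10 and 0.13. Non-robust estimates gave 36 (19 and 17; 1 at least 2-fold lower), a threshold of 0.01 gave 11 (8 and 3), glmTreat gave 3 (3 and 0), and leaving out step genes gave 7 at least 2-fold higher. The length and GC correction gave 104, with 56 higher. Without PAC-CM replicates 1, 2 and 3 there were 13, 26 and 14 calls, and without kinsenoside replicates 1, 2 and 3 there were 98, 20 and 37. Leave-one-out ranges were 13 to 98 in all, 8 to 47 higher and 5 to 51 lower, and at 2-fold 9 to 35, 8 to 22 and 1 to 13; each fit had 1 library fewer, and the cause beyond this was not tested. The share of calls that were higher was 40.8%, but 28.4% of 88 with total counts, 52.8% with non-robust estimates and 53.8% with the length and GC correction. Without PAC-CM replicates 1, 2 and 3 it was 61.5%, 57.7% and 57.1%. Without kinsenoside replicates 1, 2 and 3 it was 48.0%, 75.0% and 59.5%, so most calls were higher in 5 of these 6 fits. Hist2h2aa1, Arl2bp, Socs6 and Gm15925, whose counts jump along the groups, were among the higher calls in each of the 6. The median log2 fold change of all genes moved at most to -0.05 with total counts. RLE, upper quartile, no filter, the 1 CPM filter and leaving out the most abundant genes gave 66, 73, 105, 68 and 70. Of the 29 called named genes, 9 passed in each of the 17 alternatives that keep the 0.05 threshold and test against no change, which leaves out glmTreat (Hist2h2aa1, Arl2bp, Socs6, Clec4n, Kidins220, Ccl6, Cxcl10, Spata13 and Irf1), the other 20 in between 5 and 14, and none changed sign. Of 16 lists past the threshold (13 up, 3 down), an estimated correlation left 0 (0 up, 0 down; 6 had an unadjusted p under 0.05), fry left 6 (4 up, 2 down), and leaving out called members left 1 of the lists that were down. Leave-one-out gave 12 to 18 lists. The mitochondrially encoded list also missed with the length and GC correction (0.0612) and the autophagy list with total counts (0.0805). The fatty acid oxidation and PPAR list missed with total counts (0.0710) and without its called member (0.134). The M2 list passed in 4 of 13 alternatives, lowest without kinsenoside replicate 2 (0.00550; highest 0.489), and the chemokine receptors in 4, lowest without PAC-CM replicate 1 (0.00329; highest 0.796). Of the 18 panel genes, 3 were called in the main test, 6 by DESeq2 and 1 to 3 in leave-one-out, with 1 without PAC-CM replicate 1 or 2. The called genes were not always the same: without kinsenoside replicate 2 Tlr4 was called and Il1b was not. The first component held 28.8% over all tested genes and 28.4% over the 500 most variable. The cause of these differences was not tested. Depth limits genes at 0, which cannot be placed below 0.0632 to 0.0729 CPM.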

Other observations

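Other called genes are given here that were chosen after their values were seen. Actb, the cytoplasmic actin gene, fell from 3101 to 1977 CPM (log2 fold change -0.60, adjusted p = 0.0338). Ezr, which links actin to the membrane, fell by 0.54 and the tubulin gene Tubb6 fell by 0.40 on the log2 scale. Actb was not called by limma-voom or with non-robust estimates. With a library left out, Actb was called only without PAC-CM replicate 1, and Ezr and Tubb6 only without kinsenoside replicate 1. Pde4b, a phosphodiesterase that degrades cyclic AMP, fell by 0.60, Itpkb, an inositol trisphosphate kinase, fell by 0.48, and Orai2, a calcium channel subunit, fell by 0.69 (adjusted p between 0.0266 and 0.0353). Tnfsf10, which encodes the death ligand TRAIL, fell by 0.57 and the transcriptional repressor gene Bcl6 fell by 0.54. Rps15a, a ribosomal protein gene outside the fixed list, rose by a log2 fold change of 0.37 (adjusted p = 0.0480). Its call was lost whichever library was left out.

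The tests chosen after the result was seen were stepwise assignment for Tlr4, the overlapping gene pairs, the random lists matched on expression and length, and, for kinsenoside replicate 2, the wider check and its values against each PAC-CM library. Lists of genes related to called genes did not pass as groups. For Actb, Ezr and Tubb6, the 28 other tested genes of the actin cytoskeleton and of SRF, a transcription factor of actin genes, had a median log2 fold change of -0.0243 (SD 0.200; 10 above 0 and 18 below; camera p = 0.112 with the preset correlation). For Clec4n and Mrc1, 15 other tested genes of a C-type lectin list had a median of 0.0545 (SD 0.491, with 8 above 0 and 7 below), and the same camera test gave 0.282. That list left out Clec7a, another C-type lectin receptor, which was at 303 CPM in PAC-CM and 412 CPM with kinsenoside. Its log2 fold change was 0.49 (edgeR adjusted p = 0.0716), so the result covers the listed genes only. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real split) gave as many as 71 genes, and the highest other gave 8; the splits are too few for a share under 0.05.

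The large increases of Hist2h2aa1, Arl2bp and Socs6 may come from stepwise assignment of reads to genes that follows the groups by chance. Among 126 genes with such a jump, 4 follow the real split, against a highest value of 5 and a median of 2 over the 9 other splits. For 10 of the 126, which include both genes of some pairs, an overlapping gene goes the other way. Ube2v1 had 661 counts in PAC-CM replicate 2 and 2814 to 3644 in the other libraries, while Gm20431 had 5729 there and 0 elsewhere. Hist2h2aa1, Arl2bp and Socs6 are not among these 10. At the Hist2h2aa1 locus, Gm20634 overlaps Hist2h2aa1 and spans Hist2h3c1. Gm20634 gained 133, 119 and 100 counts where Hist2h3c1 went from 195, 163 and 184 to 68, 63 and 51. This exchange leaves the larger gain of Hist2h2aa1 without a counted source. An effect of kinsenoside on the 3 genes stays open, since jumps that follow the groups cannot be assigned from counts.

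Tlr4 was at 107 and 114 CPM in kinsenoside replicates 1 and 3 and between 17.6 and 23.2 CPM in the other 4 libraries. Stepwise assignment of reads may account for this, as 122 genes have jumps that do not follow the groups, where simulated counts gave at most 3. Those counts were drawn with the fitted trend of dispersion, so genes more variable than the trend for any reason would exceed them. The comparison thus shows an excess of jumps and cannot tell read assignment from other sources. Tlr4 is not among the genes with jumps for which an overlapping gene went the other way. No counted source of its gain was thus found. A swapped label was tested beforehand at 14 of the 20 genes called without kinsenoside replicate 2, the other 6 being genes with jumps. Jumps were sought at a highest count of at least 200, so the 14 still held Gm20634 and Phtf1os, which jump at lower counts. At 10 of the 14 (71.4%), Gm20634 among them and Phtf1os not, this library lay nearer the other kinsenoside libraries. That share lay between the bounds of 50% and 80%, as did the share at 384 of 499 genes with an unadjusted edgeR p under 0.01 (77.0%). At the same 10 genes it also lay beyond all 3 PAC-CM libraries, with Irf1 at 82.2 CPM (PAC-CM 145 to 161) and Ccl6 at 330 CPM (PAC-CM 173 to 199), which argues against a library of macrophages without kinsenoside. A difference in Tlr4 between cultures was not tested.

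The position of ribosomal protein and oxidative phosphorylation genes above other genes, with no member called over all genes, could come from a trend with transcript length or GC content, as both lists hold short transcripts (median 1109 and 1093.5 nucleotides, against 3070 for all tested genes). After removal of such trends the medians were 0.241 and 0.113, against 0.250 and 0.115 before, which argues against this trend as the whole cause. The median of all tested genes also moved, from -0.00562 to 0.0286. The position of both lists relative to all genes therefore shrank more than their own medians, and the trend may account for a part. Against 1 library alone as the cause of the ribosomal median, its lowest median with 1 library left out was 0.199, without kinsenoside replicate 3. Of 10000 random lists matched on expression and length, 0 reached the ribosomal median and 8 the oxidative phosphorylation median. The random lists' own medians were typically above 0, at 0.0624 and 0.0422. Members of a random list need not move together, while the ribosomal list had an estimated correlation of 0.651. These counts therefore cannot tell an effect of kinsenoside from a shared shift between libraries. What stays open is a difference between cultures that moves these genes together, such as RNA handling, or an effect of kinsenoside. Neither list passed camera with an estimated correlation. The estimate for the oxidative phosphorylation list was 0.0197, so its miss alone does not show correlated members.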
